A study of Mus musculus with 6 samples.

How the data were processed

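Mitral valves of K/B.g7 and B.g7 mice were digested with collagenase 2 and DNase, red cells were lysed, and live single cells were sorted, per the labels' protocols. Droplet libraries were made with a 10x Genomics single cell 3′ kit, 1 library per genotype at 3, 8 and 25 weeks, which gave 6 libraries. Per the submitters' processing notes, Cell Ranger 3.1.0 and the mm10 build were used. The annotation version and the setting of the cell caller are not given in the sources used here. The deposited values are whole-number counts of UMIs per gene and barcode, not normalized, over 31053 genes that are the same in all libraries, and 71 symbols are shared by several gene IDs and were kept apart by ID. The barcodes, gene identifiers and symbols were used as the authors deposited them. The libraries are named by genotype and age, and gene positions are from an mm10 annotation.

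The depth was 29612970, 45002210 and 69152541 UMIs in K/B.g7 at 3, 8 and 25 weeks and 15196750, 29876036 and 54850494 in B.g7. Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, which left 53526 of 58351. The automatic threshold of Scrublet marked 37 barcodes (0.0691%) and was not used. In its place the barcodes of highest Scrublet score were marked as predicted doublets in each library, at a rate of 0.8% per 1000 barcodes. These were 5655 in all and from 122 (B.g7, 3 weeks) to 3506 (K/B.g7, 25 weeks). All 53526 barcodes kept, predicted doublets included, were scaled to 10000 UMIs, log-transformed and reduced to 2000 variable genes and 30 principal components. They were clustered with 15 neighbours by the Leiden method at resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), without integration across libraries. Clusters in which at least 25% of cells had a Ptprc UMI were clustered again together.

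The 50 clusters were named from marker lists fixed before the data were examined, as were the gene lists, the rule for named genes, the tests and most of the alternatives. The thresholds for naming were set after the data were seen. They asked for at least 3 detected markers, a score of at least 0.25, at most 50% predicted doublets and at least 10 cells, with folds over a pseudocount of 20 CPM among genes seen in at least 25% of the cells. This left 6 clusters without a name. Cluster 14, led by hemoglobin genes with a median of 665 UMIs, held 73, 365 and 66 cells in K/B.g7 at 3, 8 and 25 weeks and 50, 396 and 75 in B.g7.

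Counts were summed over the cells of a class in each library and tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, R 4.3.3), with genotype and age in 1 model and age as a block. The 3 ages then stand as the replicates of genotype, with 2 residual degrees of freedom, and the same fit gave the contrast of 25 against 3 weeks. An age was left out of a class where a library had under 20 cells of it, which left 8 and 25 weeks for T cell-like cells, with 1 residual degree of freedom. The threshold was an FDR of 0.05 (Benjamini-Hochberg). Standard errors of fitted log2 fold changes were taken as the size of the change over the square root of F. The pairing comes from the age in the labels. Deviations of libraries of the same age correlated by 0.610, 0.476 and 0.197 at 3, 8 and 25 weeks in fibroblast-like cells, by 0.386, 0.239 and 0.0899 in endothelial-like and by 0.387, 0.600 and 0.202 in macrophage-like cells.

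Gene lists, 26 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation. Members were also adjusted over the list alone. Shares of cells were compared by exact permutation tests of 3 against 3 libraries, two-sided and without the pairing by age, with exact binomial 95% intervals per library. At each age, with 1 library per genotype, ratios of CPM were given without a test, with exact intervals that cover counting error only, a pseudocount of 0.5 UMIs for list medians, a floor of 3 counts for a count of 0, and percentiles among 10000 random lists drawn from 20 bins of expression.

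Named genes of the genotype comparison were up to 10 per direction of the largest fitted change past the threshold, with the same sign at all ages fitted and a mean of at least 20 CPM. Where none passed, the 5 of smallest p with 1 sign were given. Of the age comparison up to 6 per direction were named by the same rule, of each list up to 4 members of smallest p, and at each age the 5 largest ratios per direction with at least 50 CPM and 20 UMIs, leaving out mitochondrial, ribosomal, hemoglobin, immunoglobulin, sex-linked and unnamed genes. The text gives values for part of these.

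The tests were run on simulated counts with 200 changed genes. In the genotype comparison, 2-fold and 4-fold changes were recovered in 55% and 92% of genes in fibroblast-like cells (14356 genes), 28% and 88% in endothelial-like (10177 genes), 6% and 83% in macrophage-like (3892 genes) and 30% and 88% in T cell-like cells (6476 genes). In the age comparison these were 45% and 87%, 19% and 84%, and 2% and 51% in the first 3 classes. Unchanged genes were called too, 8, 7, 5 and 12 in the genotype comparison and 20, 15 and 0 in the age comparison. In the T cell-like class and in the age comparison of fibroblast-like and endothelial-like cells this is clearly more than the threshold of 0.05 allows. In the genotype comparison of the other classes it lies near that threshold.

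The alternatives were DESeq2 1.42.0, relative log expression factors, no filter on low counts, a stricter cell filter (1000 UMIs, 5% mitochondrial), predicted doublets kept, resolutions 0.5 and 2.0, equal numbers of cells, each age left out, and age or genotype left out of the model. Alternatives chosen after the data were seen were single clusters alone, cells with Xist or with Y-linked UMIs alone, T cell-like cells without clusters with Rag1 or Dntt UMIs in at least 10% of cells, other denominators of shares, and the omission of genes at higher CPM in fibroblast-like cells. For shares of cells with a Ptprc UMI each cell was thinned to 1000 UMIs, and 201, 560 and 823 shallower cells of K/B.g7 and 197, 640 and 237 of B.g7 were left out. Plots were drawn with matplotlib 3.10.9.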

Results

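Single cells of the mitral valve were compared between K/B.g7 mice, which carry the KRN T cell receptor transgene and develop autoantibody-driven arthritis with inflammation of the heart valves, and B.g7 mice, which lack the transgene and served as controls. The question was how the cell types of the valve and their expression differ in autoimmune carditis. Live single cells sorted from digested valves gave 6 droplet libraries, 1 for each genotype at 3, 8 and 25 weeks of age. The libraries held 243691001 UMIs in 58351 barcodes, from 15196750 UMIs (B.g7, 3 weeks) to 69152541 UMIs (K/B.g7, 25 weeks). In all 47871 cells were used, with a median of 2865 UMIs per cell (K/B.g7, 25 weeks) to 5606 (B.g7, 25 weeks). The labels do not give the number of mice in a library, so p-values measure only the spread between these 6 libraries. A value at a single age has no replicate. Every library held cells with Xist, the transcript of the inactive X chromosome, and cells with the Y-linked Ddx3y, from 4621 against 142 cells in B.g7 at 8 weeks to 3726 against 4102 cells in K/B.g7 at 25 weeks.

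Clusters were named from fixed marker genes into 14 classes. Interstitial fibroblast-like cells, the matrix-producing cells of the valve, made up 78.3% ± 2.76 of the cells in K/B.g7 and 72.7% ± 12.8 in B.g7 (SD, n = 3 libraries each). Endothelial-like, mural or smooth muscle-like, mesothelial-like, lymphatic endothelial-like, glial-like and melanocyte-like cells and 7 immune classes made up most of the rest. Clusters left without a name held 2.52%, 4.79% and 0.559% of the K/B.g7 cells at 3, 8 and 25 weeks and 2.27%, 7.26% and 1.03% of the B.g7 cells.

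Immune cells were a small part of the valve in both genotypes, and their share had no single direction over the 3 ages. Immune classes made up 4.95% ± 3.13 of the cells in K/B.g7 and 5.13% ± 2.56 in B.g7 (SD, n = 3), a difference of -0.184 percentage points (exact permutation test, two-sided, p = 0.9, where the smallest p that 3 against 3 libraries allow is 0.1). The pairs of libraries went in opposite directions. At 8 weeks the immune share was 8.41% in K/B.g7 (exact binomial 95% interval 7.83 to 9.02) and 5.25% in B.g7 (4.68 to 5.88). At 25 weeks it was 4.13% (3.83 to 4.44) against 7.63% (7.06 to 8.23), and at 3 weeks 2.32% against 2.52%. Macrophage-like cells also went in opposite directions at these ages, at 3.06% (2.71 to 3.45) in K/B.g7 against 1.04% (0.788 to 1.35) in B.g7 at 8 weeks. At 25 weeks they were at 0.336% (0.254 to 0.437) against 0.915% (0.719 to 1.15), and at 3 weeks at 0.956% against 0.822%. In K/B.g7 at 8 weeks 137 of the 262 macrophage-like cells lay in cluster I8, led by Il1b, the precursor of an inflammatory cytokine. In 4 of the other 5 libraries the larger part lay in cluster I4, led by C1q genes. T cell-like cells were 2.35% against 1.84% at 8 weeks and 1.60% against 4.34% at 25 weeks. Clusters I2 and I13, in which 80.4% and 90.4% of cells had UMIs of Rag1 or Dntt, genes of receptor rearrangement in developing lymphocytes, at that age held 116 and 43 of the 266 T cell-like cells in K/B.g7 and 198 and 56 of 351 in B.g7. Without these clusters the T cell-like share at 25 weeks was 0.649% against 1.24% and the immune share 3.2% (2.94 to 3.48) against 4.63% (4.18 to 5.12). Cluster I16, with such UMIs in 9.615% of its cells, lay just under the cut of 10% and stayed in. It held 7 of the 107 remaining T cell-like cells in K/B.g7 at 25 weeks and 43 of the 97 in B.g7. Mural or smooth muscle-like cells were higher in K/B.g7 at 3 of 3 ages (5.29% ± 2.51 against 2.67% ± 1.54, n = 3, exact permutation p = 0.2). Mesothelial-like cells (0.970% ± 0.765 against 3.98% ± 3.51, exact permutation p = 0.3) and NK or innate lymphoid-like cells (0.552% ± 0.202 against 0.919% ± 0.342, exact permutation p = 0.3) were lower at 3 of 3 ages. No class passed after adjustment over the classes (Benjamini-Hochberg adjusted p = 1 each). The mean immune share was higher in K/B.g7 without the 25-week libraries (5.36% against 3.89%), without the Rag1 or Dntt clusters (4.62% against 4.12%), and as the share of cells with a Ptprc UMI after each cell was thinned to 1000 UMIs (1.96% against 1.94%, where interstitial fibroblast-like cells gave 0.104% against 0.0374%). The digestion and the gate for live cells can set all these shares.

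**Figure D1:**
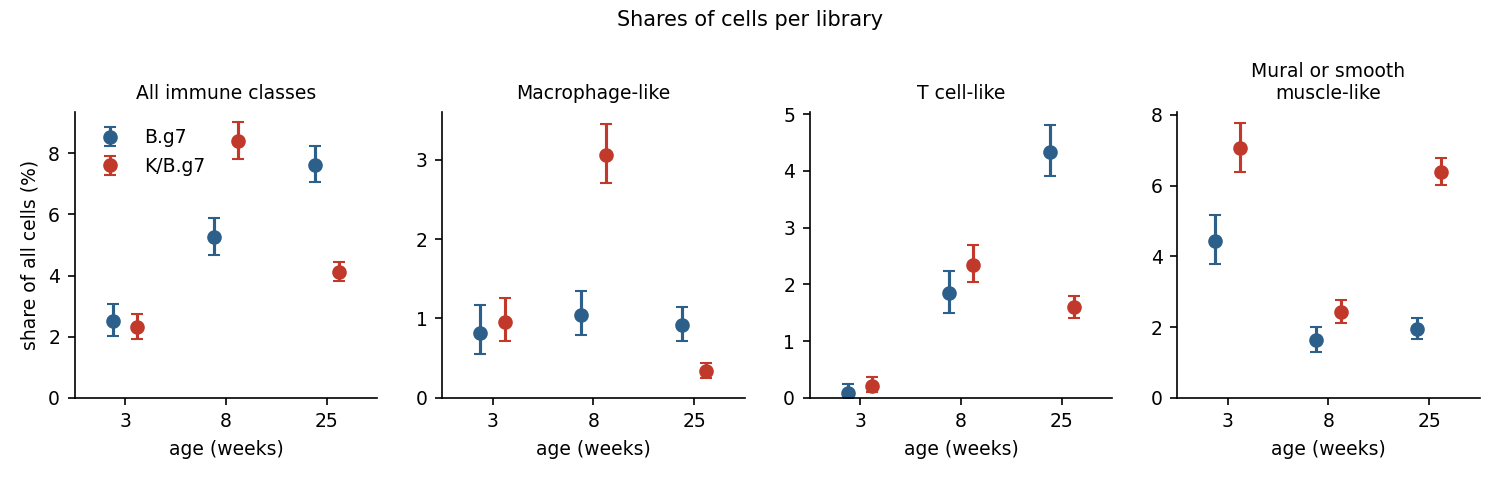
Share of all cells (%) in each library by age in weeks, for all immune classes and for the macrophage-like, T cell-like and mural or smooth muscle-like classes; points are single libraries and bars are exact 95% binomial intervals, which cover counting error only. The immune share was 8.41% in K/B.g7 against 5.25% in B.g7 at 8 weeks and 4.13% against 7.63% at 25 weeks.

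Over the 3 ages fitted together, MHC class II, type I interferon, complement, cytokine and chemokine genes rose as groups in K/B.g7 interstitial fibroblast-like cells. So did matrix, myofibroblast and cartilage genes, and transcripts of immunoglobulins, red cells and resident macrophages. Inflammatory genes, MHC class I and interferon-gamma lists included, differed mainly at 8 weeks. Their median log2 level over the mean of the libraries was 1.56 in K/B.g7 against 0.375 in B.g7 at that age. It was -0.751 against -0.719 at 3 weeks and -0.178 against -0.117 at 25 weeks. Proliferation and immediate early genes fell as groups, and no single gene passed. Of 25 lists tested, 12 rose and 2 fell by camera with its preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.487). The MHC class II list rose (adjusted p = 4.95e-07, adjusted p = 0.536 with an estimated correlation), with 7 of its 7 tested members above 0 in the fit. Cd74, the invariant chain that guides MHC class II molecules (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, build mm10), stood at 240 CPM in K/B.g7 against 26.6 CPM in B.g7 at 8 weeks and at 17.1 against 1.21 CPM at 3 weeks, but at 16.7 against 21.3 CPM at 25 weeks. Its fitted log2 fold change of 1.98 ± 0.745 (SE, n = 3) did not pass. Ctss, the lysosomal protease cathepsin S, was the 1 member past the threshold adjusted over the list alone (2.19 ± 0.518). The type I interferon list rose (adjusted p = 1.12e-04, adjusted p = 0.536 with an estimated correlation). Of its 14 members 1 passed adjusted over the list alone, the ubiquitin-like Isg15, at 49.4 against 26.1 CPM at 8 weeks and higher in K/B.g7 at 3 of 3 ages. The chemokine list rose (adjusted p = 2.68e-05, adjusted p = 0.536 with an estimated correlation). Ccl19, a ligand that draws T cells and dendritic cells and that has near-identical copies in the genome, passed adjusted over the list alone (1.26 ± 0.167, 166 against 64.3 CPM at 8 weeks and 154 against 51.2 CPM at 25 weeks). Cxcl14, a chemokine of stromal cells, was at 682 against 69.4 CPM at 8 weeks and at 31.7 against 35.4 CPM at 3 weeks. The cytokine list rose (adjusted p = 0.00235, adjusted p = 0.536 with an estimated correlation), with Nos2, the inducible nitric oxide synthase, past the threshold adjusted over the list alone (2.71 ± 0.470, 19.4 against 2.00 CPM at 8 weeks). The complement list rose (adjusted p = 0.00174, adjusted p = 0.536 with an estimated correlation) with 0 of 13 members past the threshold adjusted over the list alone.

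The MHC class I list (adjusted p = 0.334) and the interferon-gamma list (adjusted p = 0.211) did not pass in these cells, although 12 of 12 and 14 of 16 of their members were higher in K/B.g7 at 8 weeks. Without the 8-week libraries the type I interferon (adjusted p = 0.810), complement (0.926), resident macrophage (0.0742) and collagen lists (0.608) lost their call. The cytokine (0.682) and chemokine lists (0.0974) then turned downward, whereas MHC class II was still called. In cells with a Y-linked UMI alone, chosen after the data were seen, the complement (adjusted p = 0.00619), cytokine (4.32e-04) and chemokine lists (3.28e-08) fell, and the type I interferon (0.894) and resident macrophage lists (0.670) turned downward without passing. At 8 weeks this fit rests on 66 B.g7 cells whose origin was not established. In single clusters alone the type I interferon list fell in cluster 3 (adjusted p = 0.00564) and cluster 5 (0.0470), and rose in cluster 1 (0.0349) and cluster 7 (1.89e-04). The complement list in cluster 2 (0.261) and the chemokine and type I interferon lists in cluster 6 (0.721 each) turned downward without passing. Transcripts that belong to other cells moved as well. The immunoglobulin list rose (adjusted p = 2.32e-07, adjusted p = 0.487 with an estimated correlation), with Igkc, a light chain made by B cells, at 110 against 51.0 CPM at 8 weeks. So did the resident macrophage list (adjusted p = 0.00148, adjusted p = 0.487 with an estimated correlation), whose smallest-p member Mgl2, a lectin of macrophages, stayed at 0.545 against 0.0605 CPM at 8 weeks. The red cell list rose (adjusted p = 2.47e-04, adjusted p = 0.536 with an estimated correlation). The beta-globin gene Hbb-bs, one of several near-identical globin copies, was at 2168 against 14.2 CPM at 8 weeks. Marker genes of immune cells stood in the fibroblast-like cells at 0.656% of their level in immune cells in K/B.g7 and 0.277% in B.g7 at 8 weeks.

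Matrix and contractile genes formed the other part of the fibroblast difference. The myofibroblast and TGF-beta list rose (adjusted p = 2.68e-05, adjusted p = 0.487 with an estimated correlation), with 14 of 18 members above 0 in the fit. Acta2, the smooth muscle actin of contractile fibroblasts (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), was higher in K/B.g7 at 3 of 3 ages, at 285 against 127, 67.7 against 29.9 and 177 against 82.1 CPM. It passed adjusted over the list alone (log2 fold change 1.09 ± 0.168). It is also a marker of mural or smooth muscle-like cells, whose share was higher in K/B.g7 at the same 3 ages (7.06% against 4.44%, 2.42% against 1.62% and 6.39% against 1.94%), and RNA carried over from them was not tested. The chondrogenic and osteogenic list rose (adjusted p = 2.68e-05, adjusted p = 0.487 with an estimated correlation). Chondroadherin, Chad (0.94 ± 0.191), and chondromodulin, Cnmd (1.11 ± 0.218), both of cartilage, passed adjusted over the list alone. The list turned downward in cells with Xist alone (adjusted p = 0.888) and in clusters 2 (0.219) and 5 (0.344). Proteoglycans (adjusted p = 0.0207, adjusted p = 0.536 with an estimated correlation) and collagens (adjusted p = 0.0181, adjusted p = 0.550 with an estimated correlation) rose as lists. In single clusters alone the collagen list turned downward in clusters 2 (adjusted p = 0.0969), 3 (0.545), 4 (0.694), 6 (0.745) and 9 (0.866) and the proteoglycan list in clusters 2 (0.0969) and 4 (0.694). The proteoglycan list lost its call without the 3-week libraries (adjusted p = 0.530). The proliferation list fell (adjusted p = 2.68e-05, adjusted p = 0.536 with an estimated correlation), with 0 of its 17 members above 0 in the fit and Top2a, a topoisomerase of dividing cells, at 1.39 against 6.83 CPM at 25 weeks. At 3 weeks 13 of the 17 members were higher in K/B.g7 (median log2 ratio 0.29, percentile 100). The list lost its call without the 25-week libraries (adjusted p = 0.462) and turned upward in cells with Xist alone (0.888) and in clusters 2 (0.712), 4 (0.694) and 5 (0.344). The immediate early list, which responds to tissue dissociation, fell (adjusted p = 0.00905, adjusted p = 0.697 with an estimated correlation), with the heat shock gene Hspa1a at 3867 against 6840 CPM at 8 weeks. It turned upward in clusters 7 (0.452) and 12 (0.127) and lost its call without the 8-week (adjusted p = 0.483) or the 25-week libraries (0.274). The lists for leukocyte adhesion (adjusted p = 0.169), lipid-associated macrophages (0.211), matrix proteases (0.317), endothelial to mesenchymal transition (0.440), angiogenesis (0.575), T helper effectors (0.541), naive T cells (0.428), glycolysis (0.473) and cardiac muscle (0.0547) did not pass.

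Of 14356 genes tested in these cells, 0 passed an FDR of 0.05 in edgeR's quasi-likelihood test with age as a block, 945 had an unadjusted p under 0.05, and DESeq2 called 56. The 5 genes of smallest p with 1 direction at all ages, each with an edgeR adjusted p of 0.131, are given as values that did not pass. Gstp1, a glutathione transferase (ENSMUSG00000060803, chromosome 19, 4035407 to 4037985), was at 164 ± 56.2 CPM in K/B.g7 against 58.4 ± 21.3 in B.g7 (SD, n = 3, log2 fold change 1.44 ± 0.167). Its neighbour and near-identical copy Gstp2 (chromosome 19, 4040285 to 4046023) was at 13.1 ± 8.78 against 3.00 ± 1.21, so that the split of UMIs between them is uncertain. Mcpt4, a mast cell protease, was at 7.87 ± 1.27 against 27.7 ± 9.68 CPM, the membrane protein gene Mal at 6.19 ± 1.41 against 16.5 ± 3.76, and the reticulon gene Rtn1 at 31.5 ± 4.05 against 87.1 ± 33.5. Without the 8-week libraries edgeR called 59 genes and without the 25-week libraries 17. At 8 weeks the class lay in different clusters in the 2 genotypes. Cluster 9 held 1692 of 3194 B.g7 cells, and clusters 8, 2 and 20 held 1674, 1597 and 549 of 6431 K/B.g7 cells, with Mmp3 and Lcn2 among the genes leading cluster 20.

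In endothelial-like cells, of 10177 genes tested, 9 rose and 0 fell in K/B.g7 (edgeR), and 4 of them met the rule for named genes. Mfap4, a microfibril-associated matrix protein (ENSMUSG00000042436, chromosome 11, 61485431 to 61488900), was at 78.9 ± 12.5 CPM in K/B.g7 against 14.8 ± 13.7 in B.g7 (SD, n = 3, log2 fold change 2.49 ± 0.346, adjusted p = 0.0269). The complement component C3 (chromosome 17, 57203970 to 57228136) rose by 2.58 ± 0.364 (adjusted p = 0.0269). Ogn, the small proteoglycan osteoglycin, rose by 2.37 ± 0.359 (adjusted p = 0.0389) and Sfrp1, a secreted Wnt antagonist, by 2.36 ± 0.365 (adjusted p = 0.0403). At 3 weeks C3 stood at 2.65 CPM in K/B.g7 against 0 in B.g7, and Mfap4 and Ogn stood at 6.09 CPM each in B.g7. The endothelial-like sums of that age held 1130663 UMIs in K/B.g7 and 657284 in B.g7, so these values rest on few UMIs. The other 5 called genes, named after their values were seen, were Cxcl14, Dpep1, Igkc, Hbb-bt and Hba-a2. Of 19 lists tested 6 rose, those for complement (adjusted p = 2.73e-09, adjusted p = 0.256 with an estimated correlation), proteoglycans (7.81e-08, adjusted p = 0.256 with an estimated correlation), myofibroblast genes (3.59e-06, adjusted p = 0.256 with an estimated correlation), chondrogenic genes (5.13e-05, adjusted p = 0.256 with an estimated correlation), collagens (7.08e-05, adjusted p = 0.557 with an estimated correlation) and matrix proteases (0.0355, adjusted p = 0.557 with an estimated correlation). Of their tested members, 3 of 8, 4 of 13, 5 of 16, 2 of 6, 4 of 15 and 1 of 11 passed adjusted over the list alone. Among them were Serping1, an inhibitor of complement (1.14 ± 0.261), and Lox, which crosslinks collagen and elastin (1.68 ± 0.313). The MHC class II list did not pass here (adjusted p = 0.0548).

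The 4 named endothelial genes were at higher levels in fibroblast-like cells, at means of 411 (C3), 1373 (Mfap4), 770 (Ogn) and 190 CPM (Sfrp1). Fibroblast markers stood in the endothelial-like cells at 17.6% of their fibroblast level in K/B.g7 and 8.47% in B.g7 at 8 weeks. All 9 called genes were at higher mean CPM in fibroblast-like cells, so that leaving out such genes removed the called genes themselves. Of the 6627 genes that then remained 0 passed in edgeR and 284 had an unadjusted p under 0.05. Without the 3-week libraries edgeR called 2 genes, with adjusted p-values of 0.253 for C3, 0.339 for Mfap4, 0.253 for Ogn and 0.345 for Sfrp1. Without the 8-week libraries it called 94 genes, but not C3 (0.0686), and the collagen (0.587) and protease lists (0.743) lost their call. Cluster 10 held 248 of the 477 endothelial-like cells of K/B.g7 and 1019 of the 1197 of B.g7 at 8 weeks, but 115 of 254 against 25 of 114 at 3 weeks and 387 of 781 against 26 of 193 at 25 weeks.

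In macrophage-like cells of K/B.g7 valves the proliferation list rose and the MHC class II list fell, each with an adjusted p = 0.837 with an estimated correlation. The median log2 ratio of the proliferation list was 1.05 at 3, 1.45 at 8 and -0.10 at 25 weeks, when 7 of 14 members were higher. The list rose in the fit (adjusted p = 0.00150, adjusted p = 0.837 with an estimated correlation), with 2 of 14 members past the threshold adjusted over the list alone, Cenpf, a centromere protein (log2 fold change 2.90 ± 0.756), and Top2a (1.58 ± 0.451, at 137 against 51.2, 50.2 against 4.73 and 67.4 against 40.8 CPM at 3, 8 and 25 weeks). The MHC class II list fell (adjusted p = 0.00150, adjusted p = 0.837 with an estimated correlation). Cd74 was lower at 3 of 3 ages, at 7016 against 11576, 20952 against 25030 and 17258 against 25512 CPM (-0.59 ± 0.216). It passed adjusted over the list alone with H2-Eb1 (-0.63 ± 0.224), H2-Ab1 (-0.68 ± 0.245) and H2-DMb1 (-0.83 ± 0.275), chains and a loading factor of MHC class II. Of 3892 genes 1 rose in edgeR, the histone gene Hist1h2ap (chromosome 13, 21833026 to 21833507), at 108 ± 74.7 CPM against 4.18 ± 3.71 (SD, n = 3, log2 fold change 4.20 ± 0.506, adjusted p = 0.0226), which belongs to a family of near-identical copies. In B.g7 it stood at 0, 7.09 and 5.43 CPM at 3, 8 and 25 weeks. The macrophage-like sums there held 97702, 422971 and 368138 UMIs, so the call rests on few UMIs of this gene in B.g7. The proteoglycan list rose too (adjusted p = 1.63e-10, adjusted p = 0.837 with an estimated correlation, 5 of 5 members adjusted over the list alone), but its members were at far higher levels in fibroblast-like cells, Lum at a mean of 2778 CPM there. Without the 3-week libraries 0 genes passed in edgeR, with an adjusted p of 0.351 for Hist1h2ap, and the proliferation list lost its call (adjusted p = 0.185). In all 2 genes were called without the 8-week and 32 without the 25-week libraries. With 30 to 262 cells per library, a simulated 2-fold change was recovered in 6% of genes.

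T cell-like cells could be compared at 8 and 25 weeks only (n = 2 libraries per genotype), and effector genes of helper and regulatory T cells rose in K/B.g7 as a list (adjusted p = 0.0414, adjusted p = 0.665 with an estimated correlation). Of its 17 members 0 passed adjusted over the list alone. Il17a, a cytokine of T helper cells, was at 65.2 against 14.9 CPM at 8 weeks and 19.6 against 13.4 CPM at 25 weeks, the inhibitory receptor gene Ctla4 at 517 against 286 and 30.5 against 14.5 CPM, and Foxp3, the transcription factor of regulatory T cells, at 56.5 against 23.8 and 4.36 against 0 CPM. The T cell-like sums at 25 weeks held 459161 UMIs in K/B.g7 and 896951 in B.g7, so these values at 25 weeks rest on few UMIs. Without the Rag1 or Dntt clusters the list did not pass (adjusted p = 0.143). Of 6476 genes 0 passed in edgeR, 396 had an unadjusted p under 0.05 and DESeq2 called 1. Among the genes of smallest p were matrix genes of fibroblast-like cells, Ogn (71.9 ± 70.9 against 8.18 ± 7.35 CPM, SD, n = 2, edgeR adjusted p = 0.126), Dcn (701 ± 404 against 184 ± 96.0 CPM, adjusted p = 0.126, with a mean of 13352 CPM in fibroblast-like cells), Prg4 and Col1a2. The lists for proteoglycans (adjusted p = 1.16e-29, adjusted p = 0.506 with an estimated correlation), myofibroblast genes (2.08e-08, adjusted p = 0.506 with an estimated correlation), matrix proteases (6.80e-08, adjusted p = 0.506 with an estimated correlation), endothelial to mesenchymal transition (0.00364, adjusted p = 0.639 with an estimated correlation) and chemokines (0.00410, adjusted p = 0.896 with an estimated correlation) rose. The rise of the chemokine list rested on 1 pair of libraries, with 5 of 5 members higher at 25 weeks (median log2 ratio 1.65) and 1 of 5 at 8 weeks (-0.04).

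Between 3 and 25 weeks, with the genotypes held in the model, the matrix genes Col2a1, Eln, Cthrc1 and Col11a1 fell and the enzyme genes Inmt, Ces1d and Hsd11b1 rose in interstitial fibroblast-like cells. No gene list was tested for age. Of 14356 genes, 42 rose and 26 fell (edgeR quasi-likelihood test, 2 libraries per age). On simulated counts this test called 20 unchanged genes beside 45% of 100 genes changed 2-fold and 87% of 100 changed 4-fold, more than its threshold allows. Col2a1, the fibrillar collagen of cartilage (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695), fell from 64.9 ± 49.9 CPM at 3 weeks to 0.739 ± 0.253 at 25 weeks (SD, n = 2, log2 fold change -6.24 ± 0.568, adjusted p = 0.0102). Eln, which encodes elastin (chromosome 5, 134702593 to 134747323), fell from 1468 ± 828 to 256.1 ± 5.50 CPM (-2.45 ± 0.388, adjusted p = 0.0487). Among the other 4 genes named as falling, Cthrc1, a secreted protein of collagen-producing cells, fell by 3.08 ± 0.421 (adjusted p = 0.0339), the carboxypeptidase gene Cpz by 3.26 ± 0.455 (0.0359). C1qtnf6 fell by 2.16 ± 0.274 (0.0248) and the minor fibrillar collagen gene Col11a1 by 1.49 ± 0.234 (0.0486). Inmt, a methyltransferase of small amines (ENSMUSG00000003477, chromosome 6, 55170626 to 55175043), rose from 7.29 ± 3.25 to 90.6 ± 7.51 CPM (3.68 ± 0.326, adjusted p = 0.0102), and the carboxylesterase gene Ces1d by 2.45 ± 0.214 (0.0102). Hsd11b1, whose enzyme regenerates active glucocorticoid, rose from 9.73 ± 0.454 to 59.6 ± 22.8 CPM (2.56 ± 0.315, 0.0231). Mt1, a metal-binding metallothionein, rose from 563 ± 62.6 to 2315 ± 265 CPM (2.03 ± 0.287, 0.0359). AW112010 (2.22 ± 0.290, 0.0282) and Mndal (2.02 ± 0.218, 0.0186), both inducible by interferon, completed the 6 named as rising. Most of the change in the named genes was reached by 8 weeks, and several then moved back. Mean CPM at 3, 8 and 25 weeks was 1468, 89.1 and 256.1 for Eln. It was 59.1, 5.63 and 21.3 for Col11a1 and 8.73, 91.35 and 40.6 for AW112010. After 8 weeks only Mt1 (1754 to 2315 CPM), Cpz (6.29 to 5.79) and Cthrc1 (9.82 to 9.25) went on in the same direction. Without the 8-week libraries 976 genes were called, all 68 among them, and DESeq2 called 522. With genotype left out of the model 19 were called, which ended the calls of Hsd11b1 (0.0767), Mndal (0.0741), Cpz (0.0697), Cthrc1 (0.0767), Eln (0.0690) and Col11a1 (0.142).

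The age comparison was also run in cells with Xist and in cells with a Y-linked UMI alone, which was chosen after the data were seen. At 3 weeks in K/B.g7, Col2a1 stood at 260 CPM in fibroblast-like cells with a Y-linked UMI and at 0.639 CPM in those with Xist. At 25 weeks Inmt stood at 113 (K/B.g7) and 182 CPM (B.g7) in cells with a Y-linked UMI and at 21.7 and 22.5 CPM in those with Xist. At the other ages Inmt had no single order. It stood at 83.5 CPM with a Y-linked UMI against 131.5 with Xist in K/B.g7 at 8 weeks and at 289 against 72.2 in B.g7, and at 3 weeks at 2.46 against 6.30 and 2.44 against 19.9. In the cells with Xist alone, 111 genes were called, 33 of the 68 among them, and Col2a1 (log2 fold change -0.12, edgeR adjusted p = 0.971), Inmt (0.89, 0.362), Mt1 (0.69, 0.291), AW112010 (1.63, 0.0674) and Col11a1 (-0.46, 0.611) did not pass. In the cells with a Y-linked UMI alone, 539 genes were called, 59 of the 68 among them. Whether the age difference itself differs between these cells was not tested. The class also lay in different clusters at the 2 ages. Cluster 5 held 2000 of 4344 K/B.g7 and 1080 of 3016 B.g7 cells at 3 weeks. Clusters 3 and 2, the latter led in part by Inmt, held 3266 and 2806 of 13299 K/B.g7 cells at 25 weeks, and clusters 1 and 3 held 1267 and 909 of 6255 B.g7 cells at 25 weeks.

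**Figure D2:**
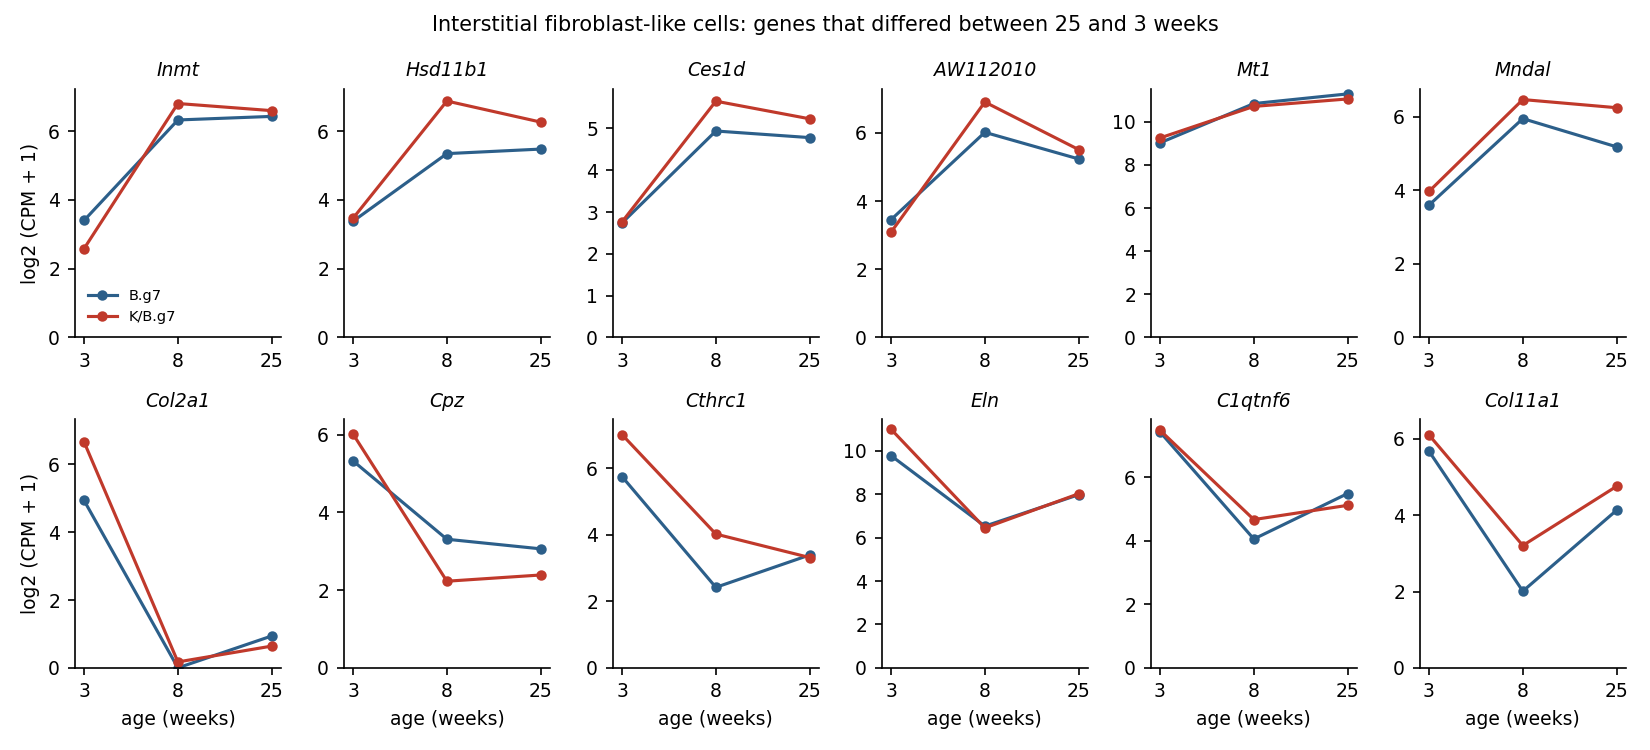
The 12 genes named between 25 and 3 weeks in interstitial fibroblast-like cells, as log2 (CPM + 1) against age in weeks (evenly spaced), 1 point per library, with lines joining the libraries of a genotype. Col2a1 fell from 64.9 ± 49.9 to 0.739 ± 0.253 CPM and Inmt rose from 7.29 ± 3.25 to 90.6 ± 7.51 CPM (SD, n = 2).

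In endothelial-like cells 0 of 10177 genes passed between 3 and 25 weeks in edgeR, 1158 had an unadjusted p under 0.05 and DESeq2 called 31. Eln had the smallest p (log2 fold change -2.11 ± 0.312, SE, edgeR adjusted p = 0.0959, n = 2 libraries per age), and the drug efflux pump gene Abcb1a was at 10.3 CPM at 3 weeks and 53.3 CPM at 25 weeks (2.34 ± 0.354, adjusted p = 0.0959). Without the 8-week libraries 174 genes were called. In macrophage-like cells 1 of 3892 genes passed, Bgn, the matrix proteoglycan biglycan, which rose from 18.3 ± 11.4 to 210 ± 132 CPM (3.70 ± 0.483, adjusted p = 0.0479, SD, n = 2) and stood at a mean of 2969 CPM in fibroblast-like cells. Leaving out genes at higher CPM in fibroblast-like cells removed Bgn itself, and 0 of the remaining genes passed in edgeR. Without the 8-week libraries 26 genes were called, against 39 in DESeq2 and 378 at an unadjusted p under 0.05 in edgeR with all libraries.

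At each age 1 library per genotype was compared, without a test, and the inflammatory genes of fibroblast-like cells differed most at 8 weeks. The median log2 ratio over 84 members of the 7 inflammatory lists was 1.24 at 8 weeks (bootstrap interval over members 0.93 to 1.49, 80 of 84 higher in K/B.g7), 0.12 at 3 weeks (49 higher) and -0.17 at 25 weeks (35 higher). By list, the 8-week medians were 2.90 for cytokines, 2.38 for MHC class II, 1.49 for chemokines, 1.38 for complement, 1.24 for interferon-gamma, 0.93 for type I interferon and 0.82 for MHC class I genes, each at percentile 100 among 10000 random lists of like expression. At 25 weeks those of MHC class II (-0.45), cytokines (-0.29) and interferon-gamma genes (-0.32) lay at percentiles 0.14, 2.12 and 0.01. Hp, the acute phase protein haptoglobin, was at 140 CPM in K/B.g7 against 0.363 in B.g7 at 8 weeks (385-fold, exact interval 177 to 1049, counting error only), and Lcn2, a siderophore-binding protein, at 574 against 18.0 CPM (31.9-fold, 28.5 to 35.9). The matrix protease Mmp3 was at 1140 against 60.2 CPM (18.9-fold, 17.8 to 20.2), and the T cell-attracting Ccl5 at 56.5 against 4.54 CPM (12.5-fold, 9.88 to 15.9). Igfbp3, a binding protein of insulin-like growth factors, was at 92.5 against 1088 CPM, 11.8-fold lower in K/B.g7 (11.3 to 12.3), and Smad6, an inhibitor of BMP signalling, 10.9-fold lower (9.39 to 12.8). Cluster 9, led in part by Igfbp3, and clusters 8, 2 and 20 hold the larger parts of the class at this age in B.g7 and K/B.g7. In cells with a Y-linked UMI, of which B.g7 had 66 and K/B.g7 1552 at 8 weeks, the median ratio turned to -0.84, and in cells with Xist it was 1.47. Of these 66 cells 29 lay in clusters 2, 8 or 20 and 1 in cluster 9, unlike the other B.g7 cells of that age, so that -0.84 rests on few cells whose origin was not established.

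At 3 weeks the nucleoside kinase gene Nme2, which shares most of its 3′ end with other genes, was 5.68-fold higher in K/B.g7 fibroblast-like cells (4.82 to 6.74), the neuropeptide gene Npy 4.51-fold (4.06 to 5.02, when the unnamed cluster 35, led in part by Npy with a median of 33098 UMIs per cell, held 64 cells in K/B.g7 and 31 in B.g7) and Col2a1 3.38-fold (3.00 to 3.82). In cells with a Y-linked UMI, Col2a1 then stood at 260 CPM in K/B.g7 against 14.6 in B.g7. In cells with Xist it stood at 0.639 against 0.816 CPM. Fabp4, a fatty acid carrier, was 5.35-fold lower in K/B.g7 fibroblast-like cells at 3 weeks (4.67 to 6.13). At 25 weeks Sult1e1, an estrogen sulfotransferase, was at 2.07 against 82.8 CPM, 40.1-fold lower (32.3 to 50.3). Cluster 29, led in part by Sult1e1, then held 2 cells in K/B.g7 and 229 in B.g7. Calcrl, a receptor for calcitonin-like peptides, was 3.21-fold higher (3.03 to 3.40). In endothelial-like cells at 8 weeks Nppc, the precursor of C-type natriuretic peptide, was at 265 against 7.81 CPM (33.9-fold higher, 24.4 to 48.6) and Adamts8, a matrix protease, at 112 against 2.06 CPM (54.6-fold, 29.1 to 116). At 25 weeks Nppc was 4.57-fold lower in K/B.g7 (3.41 to 6.19). In the same cells at 25 weeks Plagl1, an imprinted zinc finger gene, was 9.95-fold higher (7.68 to 13.1) and Acta2 10.2-fold higher (6.24 to 17.7), with Ccl5 55.2-fold lower (24.9 to 153). At that age cluster 10 held 387 of 781 of these cells in K/B.g7 and 26 of 193 in B.g7, and cluster 13 held 394 and 167. Mural or smooth muscle-like cells, whose markers include Acta2, were 6.39% and 1.94% of all cells, and their marker Tagln was 10.6-fold higher in the endothelial-like cells (5.98 to 20.9). In macrophage-like cells Retnla, a marker of alternative activation, was 4.59-fold lower in K/B.g7 at 3 weeks (4.13 to 5.12) and at 901 against 12596 CPM at 25 weeks (14.0-fold lower, 11.5 to 17.1). Cluster I17, led by Retnla, then held 2 of 56 cells in K/B.g7 and 18 of 74 in B.g7. Cd207, which encodes langerin, was 12.8-fold lower at 8 weeks (7.94 to 21.6) and, with 0 UMIs in K/B.g7, at least 9.35-fold lower at 25 weeks against a floor of 3 counts. In T cell-like cells most of the largest ratios were those of genes of fibroblast-like or mural cells, so that RNA carried over from them was not excluded. At 8 weeks Col1a1 was 29.7-fold higher in K/B.g7 (5.13 to 1190), Prg4 8.75-fold and Col1a2 6.44-fold, at means of 2503, 782 and 2499 CPM in fibroblast-like cells. Cxcl10, a ligand induced by interferon-gamma, was 11.3-fold higher (5.34 to 28.4) and at a mean of 61.8 CPM in fibroblast-like cells. At 25 weeks Ogn was 9.12-fold higher (4.83 to 18.7), Mmp2 7.81-fold, Fmod 7.49-fold and Tagln 6.91-fold, and the next was Gzmb, the cytotoxic granule protease (6.38-fold, 3.52 to 12.3).

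**Figure D3:**
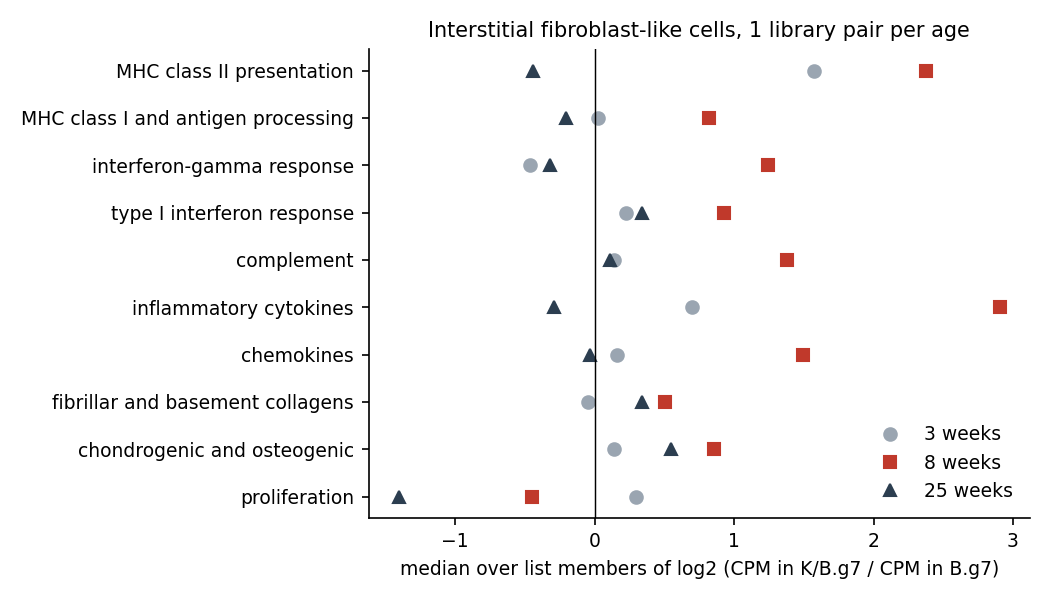
Median over list members of the log2 ratio of CPM in K/B.g7 to CPM in B.g7, for 10 gene lists in interstitial fibroblast-like cells at 3, 8 and 25 weeks, with 1 pair of libraries per age and no test. At 8 weeks the medians of the 7 inflammatory lists lie between 0.82 and 2.90, and at 25 weeks that of MHC class II lies at -0.45.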

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

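The items below set side by side genotype differences that had opposite signs at 2 ages, each from 1 pair of libraries, and none of these differences between ages was tested. The analyses of cells with Xist or with Y-linked UMIs alone were chosen after the data were seen, and the tests of the other explanations were written before their results were seen.

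The log2 ratio of the immune share in K/B.g7 to that in B.g7 was 0.68 at 8 weeks and -0.89 at 25 weeks, 1.565 apart, and that of macrophage-like cells was 1.56 and -1.44, 3.00 apart. In interstitial fibroblast-like cells the median log2 ratio of the MHC class II list was 2.38 at 8 and -0.45 at 25 weeks (a difference of 2.83), and that of the cytokine list 2.90 and -0.29 (3.197). The interferon-gamma list had a median of -0.47 at 3 and 1.24 at 8 weeks (-1.71), and the immunoglobulin list -0.90 and 2.51 (-3.41). The proliferation list went from 0.29 at 3 to -1.41 at 25 weeks (1.70) and the immediate early list from 0.26 at 3 to -0.42 at 8 weeks (0.68). The list for endothelial to mesenchymal transition was at -0.22 at 8 and 0.36 at 25 weeks (-0.59), and that for angiogenesis at -0.38 at 3 and 0.53 at 25 weeks (-0.90).

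Inflammatory genes in fibroblast-like cells at 8 weeks stood highest over B.g7, with a median log2 ratio of 1.24 over 84 members. Free RNA at the level of pooled immune markers was argued against for the lists without MHC class II. Over their 77 members the CPM gained was a median of 68.8 times what such RNA would give (bootstrap interval 33.7 to 127). Members that gained without a modelled rise were given the highest ratio seen, and a few such as Il1b stayed below what free RNA would give. Over 7 MHC class II members the ratio was 3.70 (2.83 to 4.34), above the bound of 2 set beforehand. The level was 1 fixed value per library and the intervals cover list members only. Carry-over from single immune types was not modelled, so 3.70 does not decide the MHC class II genes. A difference in the sex of the pooled animals as the whole source was argued against by a median of 1.47 in cells with Xist alone (1.12 to 1.88), but the median was -0.84 in cells with a Y-linked UMI (-1.36 to -0.43), of which B.g7 had 66. A shift of cells between fibroblast-like clusters stays open, because the median within clusters was 0.39 (0.15 to 0.86, above 0 in 9 of 10 clusters) and its interval includes 0.62, the bound set at 0.5 of the whole difference. The clusters were formed from expression itself, without integration across libraries. A change within cells can then also move them to other clusters, so this test cannot separate such a change from a shift. The disease of the K/B.g7 valve at that age may contribute and was not tested apart from these.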

How the results depend on the processing

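The analyses of single clusters, of cells with Xist or with Y-linked UMIs, without genes at higher CPM in fibroblast-like cells, and without Rag1 or Dntt clusters were chosen after the data were seen. Among gene lists called in the 4 classes, 285 values under the alternatives run kept their direction and side of the threshold, 62 lost the call and 9 turned, single clusters not counted. In single clusters alone, of 82 values over 9 fibroblast-like clusters 26 kept both, 37 lost the call and 19 turned, and of 11 values over 2 endothelial-like clusters 9 kept both, 2 lost the call and 0 turned. Among named genes 367 kept both, 65 lost and 90 gained a call, and 0 turned. The naming rule already asked for the same sign in all pairs of libraries compared, which the gene lists did not have to meet. Leaving out an age or changing the model could then hardly turn a named gene, so the 0 does not measure how stable the directions are. The cause of the changes was not tested, except that leaving out an age or taking single clusters leaves fewer cells or libraries, and omitting genes leaves fewer to test.

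Genotype in fibroblast-like cells gave 0 genes, but 56 with DESeq2, 222 with no filter, 4 with equal numbers of cells, 0 to 59 with an age left out, 28 in cells with a Y-linked UMI, and 19, 93, 73, 16, 21, 26, 40 and 4 in clusters 1, 2, 3, 4, 5, 6, 7 and 9 alone. In endothelial-like cells the 9 genes became 5 with relative log expression factors, 5 with equal cells, 115 with no filter, 38 with doublets kept, 0 without genes at higher CPM in fibroblast-like cells (which takes out the 9 themselves), 2 to 94 with an age left out, and 23 and 28 in clusters 10 and 13. In macrophage-like cells the 1 gene became 2 at resolution 0.5, 0 with equal cells, 30 with no filter, 14 with doublets kept and 0 to 32 with an age left out. In T cell-like cells 0 became 1 with DESeq2, 3 and 4 at resolutions 0.5 and 2.0, 4 with equal cells, 82 with no filter, 46 with doublets kept, 47 with the stricter cell filter and 3 without Rag1 or Dntt clusters.

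The 68 genes between 25 and 3 weeks in fibroblast-like cells became 522 with DESeq2, 1176 with no filter, 168 with equal cells, 19 with genotype left out, 976 without the 8-week libraries, 111 and 539 in cells with Xist and with a Y-linked UMI, and 278, 170, 435, 333, 142, 252 and 41 in clusters 1, 2, 3, 4, 5, 6 and 9. In endothelial-like cells 0 became 31 with DESeq2, 201 with no filter, 42 with doublets kept, 174 without the 8-week libraries, 4 and 13 in cells with Xist and with a Y-linked UMI, and 27 and 49 in clusters 10 and 13. In macrophage-like cells 1 became 39 with DESeq2, 48 with no filter, 25 with doublets kept, 26 without the 8-week libraries, and 0 with relative log expression factors, resolution 0.5 or 2.0, equal cells, genotype left out, the stricter filter, or without genes at higher CPM in fibroblast-like cells.

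The 29 list calls over the 4 classes became 0 with an estimated correlation, 50 with no filter, 19 without genes at higher CPM in fibroblast-like cells and 19 to 36 with an age left out. The 19 without such genes include the 14 calls of fibroblast-like cells, which that setting leaves as they are. Of the calls in the other classes only 3 could be tested again, and these stayed. The T cell-like class entered the totals with an age left out only without 3 weeks, with its main calls. In fibroblast-like cells with a Y-linked UMI the type I interferon (adjusted p = 0.894), complement (0.00619), cytokine (4.32e-04), chemokine (3.28e-08) and resident macrophage lists (0.670) turned downward. In those with Xist the chondrogenic list turned downward and the proliferation list upward (0.888 each). With an age left out the cytokine list ran from an adjusted p of 3.79e-10 upward (without 25 weeks) to 0.682 downward (without 8 weeks), and the chemokine list from 2.64e-16 upward to 0.0974 downward.

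Without the replicate block of age, 0 genes passed between genotypes in endothelial-like and 0 in macrophage-like cells, and 17 lists. The block changed the call of C3, Mfap4, Ogn, Sfrp1 and Hist1h2ap (adjusted p = 0.999 each without it) and of the fibroblast type I interferon (0.0581), complement (0.0759), cytokine (0.160), collagen (0.295) and proteoglycan lists (0.272), the endothelial chondrogenic list (0.110), the macrophage MHC class II and proliferation lists (0.119 each), and the T cell chemokine (0.295) and T helper lists (0.315), and 2 of the 29 lists were not tested without it. It changed no other call of a list.

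The difference in immune share turned to 1.48 percentage points with the 25-week libraries left out, where the values with an age left out ran from -1.85 to 1.48, to 0.0220 for thinned cells with a Ptprc UMI, and to 0.499 without Rag1 or Dntt clusters. The 8-week median of 84 inflammatory genes, 1.24, turned to -0.84 in cells with a Y-linked UMI. In T cell-like cells leaving out an age was not run, since the 3-week libraries were already out and leaving out another leaves 1 age, and the age comparison without either genotype leaves 1 library per age. Few cells limit the macrophage-like class, at 30 to 262 cells per library, and the T cell-like class, whose 11 and 3 cells at 3 weeks were left out.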

Other observations

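The counts over other splits of the 6 libraries were chosen after the genotype results were seen, as were the looks at single clusters and at cells with Xist or with Y-linked UMIs, and the tests of near-identical copies, of chromosome 19 and of free fibroblast RNA were written before their results were seen. The verdict on how reads of copies were assigned was changed afterwards.

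Cells with transcripts of neuronal genes came mainly from young valves. Cluster 35, left without a name, was led by Cartpt, Prph, Stmn2 and Npy, genes of neurons and their peptides, and held 64 cells in K/B.g7 and 31 in B.g7 at 3 weeks, 4 and 1 at 8 weeks and 0 at 25 weeks in both, with a median of 33098 UMIs per cell. Of the 582 mesothelial-like cells of cluster 19, led by Upk3b and Nkain4, 563 came from B.g7 at 25 weeks, so that the cluster stands for that library as much as for a cell type. Melanocyte-like cells, led by Dct and Pmel, were found in all 6 libraries, from 4 (B.g7, 8 weeks) to 58 cells (K/B.g7, 8 weeks).

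In B.g7 at 8 weeks the few fibroblast-like cells with a Y-linked UMI lay in other clusters than those with Xist. Of 66 such cells 29 (43.9%) were in clusters 2, 8 or 20 and 1 (1.52%) in cluster 9, against 177 (5.88%) and 1657 (55.1%) of 3010 cells with Xist. In K/B.g7 at 8 weeks 54.1% of the 1552 cells with a Y-linked UMI and 64.0% of the 3437 cells with Xist were in clusters 2, 8 or 20. None of the 66 barcodes (0) also occurred in the K/B.g7 library of that age, against 9 of the 3010, and their median was 5216.5 UMIs. Whether they belong to the valves of that library was not tested. Relative to the mean of the 6 libraries, the inflammatory genes stood at a median log2 level of 1.96 in these 66 cells, 1.27 in K/B.g7 cells with a Y-linked UMI, 0.27 in B.g7 cells with Xist and 1.72 in K/B.g7 cells with Xist.

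The 9 genes that rose in endothelial-like cells had a median log2 ratio of 2.498, and free RNA from fibroblast-like cells is a candidate explanation for part of them. Igkc, Hbb-bt and Hba-a2 among them are transcripts of B cells and red cells, so RNA made by fibroblast-like cells is not their source. The pool used below also holds B cell-like cells, which make Igkc, so its values do not test fibroblast RNA alone. Fibroblast markers stood at 7.91% of their fibroblast level in the other classes of K/B.g7 and 3.59% in B.g7 at 8 weeks, and at 9.51% and 4.02% at 25 weeks. In a pool of glial-like, lymphatic endothelial-like and lymphocyte-like cells the same 9 genes had a median log2 ratio over the ages of 1.58 (bootstrap interval over genes 0.72 to 2.73), with 9 of 9 higher in K/B.g7. Since this interval includes the bound of 1.25, set at 0.5 of the endothelial value, the free RNA and a change in the endothelial-like cells cannot be told apart.

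In fibroblast-like cells 222 genes differed by at least 1.5-fold with the same sign at all 3 ages, among them Gstp1, Grcc10 and Nme2. Apart from Gstp1 and Gstp2, only 16 of them had a mean of 20 CPM or more. How many of the lower genes pass by counting error alone was not tested. Of all 222, 14.9% (33) had at least 50% of the 31-mers of their 3′ end in transcripts of other genes. Of the rest 2.90% (409 of 14115) did (Fisher's exact test, p = 5.06e-14), so reads shared with near-identical copies may account for part of the 222. Whether reads of copies were assigned differently in the genotypes stays open. Among the other genes at a mean of 20 CPM or more, 12.1% of the 132 with a shared 3′ end were higher in K/B.g7 at all 3 ages, against 12.8% of the 5603 without one (Fisher's exact test, p = 1). This met the bound set beforehand against such a difference, but the bound was wrong, since leaving out the genes chosen for their difference also takes out the copies it would have moved. After the result was seen the verdict was therefore changed from against to open. A stretch of chromosome 19 within 10 Mb of Gstp1 held 3.64% (8 of 220) against 1.48% of the others (Fisher's exact test, p = 0.0190), but 1 of 16 at a mean of 20 CPM or more (6.25% against 1.69%, p = 0.241), so linked strain differences remain a candidate explanation for few of the genes.

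The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. Splits that part the libraries of only 1 age occur 2 times each with the same fit once age is in the model. They also hold the genotype difference at that age, so the numbers of splits as large do not measure chance. In fibroblast-like cells the genotypes gave 0 genes and the highest other split 75, where 10 of the 10 splits are as large because the real count is 0, and 14 lists against 18, with 4 splits as large. In endothelial-like cells they gave 9 genes against 76 (4 splits as large) and 6 lists against 12 (5 splits), and in macrophage-like cells 1 gene against 35 (3 splits) and 3 lists against 7 (7 splits). Among the 4 splits that part the libraries of every age, as the real one does, the highest others were 0 genes and 18 lists, 15 genes and 5 lists, and 0 genes and 4 lists. The splits with the highest gene counts part only the 8-week pair once age is in the model. Each is then the difference between K/B.g7 and B.g7 at 8 weeks, 1 library against 1, and gives no comparison by chance. At an unadjusted p under 0.05 the order was another, with 1078, 623 and 175 genes in these splits and 1174, 868 and 428 in those that part only the 25-week pair, of which 0 passed the threshold, so no age is singled out.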
